A study of Homo sapiens with 11 samples.

How the data were processed

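Pooled total RNA was measured on 11 Illumina bead arrays, 3 labelled as erythroid cultures from CD34+ cells and 8 labelled as bone marrow stromal cells of donors A and B. Per the labels, RNA was purified on Qiagen columns, checked on a Bioanalyzer and converted to biotinylated cRNA with an Ambion kit, each array received RNA pooled from 2 biological replicates, and cultures lasted 7 days. The authors summarised each probe on each array in GenomeStudio (version not given) per the submitters' processing notes, and the non-normalized table they deposited holds the mean bead intensity per probe. These deposited intensities never fell below 79.91 and had medians from 102.6 to 122.9, so no background had been subtracted and the arrays had not been normalised to each other. The deposited detection p-value of each probe, per the file headers, ranks its signal among the negative control beads of the same array, in steps of 1 in 770. The standard error of the bead intensities and the number of beads behind each probe were also deposited as GenomeStudio wrote them, with a median of 21 to 22 beads. A processed table of intensities was deposited as well, which the authors had quantile normalised over all 11 arrays on the linear scale, although the labels do not state the step. Its sorted columns differed from their median by at most 0.507%, and that median from the mean of the sorted non-normalized columns by at most 0.126%, against 3.51% for their geometric mean. Non-normalized columns scaled to 1 median differed by up to 43.7%.

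All comparisons started from the non-normalized intensities. Background was corrected with the normexp model of limma 3.58.1, with negative control levels inferred from the detection p-values and an offset of 16. Values were quantile normalised on the linear scale, over the 8 arrays labelled stromal or over the 3 labelled erythroid, and then taken to log2. R 4.3.3 and the data.table package (version 1.17.8) were used for the computation, and Python 3.11.15 with matplotlib 3.10.9 for the figures. Of the probes, 44051 carried a gene symbol and 3270 did not, and 35670 were matched to the current symbol by gene ID while 8381 kept the symbol of the file. The 239 probes for XIST, TSIX and Y-linked genes were left out, and 1 probe per gene was kept, that with the highest mean. Stromal genes were tested when their detection p was under 0.05 on at least 2 of the 8 arrays, which left 16300 genes, and erythroid genes were compared when it was under 0.01 on at least 1 of the arrays compared.

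Samples were grouped by label and no array was regrouped. Stromal groups were fitted in limma with 4 group means, and the averaged ACE-011 effect, the effect in each donor and the difference between donors were tested two-sided with moderated variances (4 residual degrees of freedom, prior 2.14) and Benjamini-Hochberg adjustment over all genes at 0.05. Erythroid groups had 1 array each, so log2 differences of at least 1 (2-fold) were counted without a test and set beside the same count between arrays of the stromal groups. A gene not above background on 1 of the arrays was given a fold bound against the background level of that array. The choices of fit, threshold, gene lists and named genes were made before the data were examined. There were 39 gene lists with 852 members, 848 of which had a probe. Lists with at least 5 genes were tested with camera (preset correlation 0.01, then an estimated one) and fry in limma for stromal cells, and placed among 10000 random lists of the same size and intensity for the erythroid arrays, with percentiles 2.5 and 97.5 as limits. The named genes were to be the 12 largest changes each way past the threshold in the averaged contrast, or, with none past it, the 5 smallest p each way, the 12 largest differences each way in the first 2 erythroid comparisons and the 5 largest in the third, up to 4 members per list and any tested member of the activin list. Placeholder symbols were not named.

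The alternatives were normexp without negative controls (offset 50), no background correction, median scaling, quantile normalisation over all 11 arrays, the authors' processed table, no filter or a strict one (detection p under 0.01), the mean of a gene's probes, trend and robust variances, array weights, other designs, a fold limit, leaving out each stromal array, and size limits of 1.5-fold and 3-fold. Leaving out the stromal-labelled array of the other profile was added after seeing the data. Gene lists and markers served to check labels, and arrays were also compared by correlation across 13796 genes, which are not independent replicates. The fit was tested on simulated data with changes planted in the stromal design. The first simulation took each gene's own spread within the labelled groups (median SD 0.32), the array of the other profile included. With it the fit called 0 of 67 genes planted at 1.5-fold, 5 of 67 at 2-fold and 34 of 66 at 4-fold, with 2 false calls. With each gene's spread between the closest array pairs (median SD 0.111) it called 51, 64 and 66 of them, with 10 false calls. Which donor's stroma conditioned the media is not in the labels. Bead arrays give no counts, so the number of arrays limits the precision.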

Results

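Gene expression was measured in 11 human RNA samples on Illumina bead arrays with probes for 30431 named genes. Of these arrays, 8 were labelled as bone marrow stromal cells of 2 donors, here A and B, kept for 7 days without or with ACE-011 at 100 µg/ml, with 2 arrays in each of the 4 groups. ACE-011, or sotatercept, is a soluble form of the activin type IIA receptor that traps activins and related growth factors. The other 3 arrays were labelled as erythroid cultures grown for 7 days from bone marrow CD34+ cells, with 1 array per medium. The media were a standard medium, a medium conditioned by untreated stromal cells and a medium conditioned by ACE-011-treated stromal cells. The RNA on each array was a pool of 2 biological replicates, so the spread between arrays is a spread between pools, and all p-values below measure only the spread between these samples. Between 14726 and 17368 probes per array had a detection p under 0.01, the median signal ran from 102.6 to 122.9 and the arrays held 1024476 to 1071237 beads. The number of arrays limits the precision.

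Markers of both cell types were read before any comparison. Globin genes, which encode the haemoglobin chains, and stromal genes such as COL1A1, COL1A2 and LUM, which encode collagens and a matrix proteoglycan, separated 8 arrays with a stromal profile from 3 with an erythroid profile. COL1A1 stood between 13.05 and 13.96 (log2) on the 8 arrays with the stromal profile and between 4.45 and 5.20 on the other 3. HBB, the adult beta-globin, stood between 4.74 and 6.83 on the former and between 12.39 and 14.31 on the latter. The marker profile of 2 arrays was that of the other cell type than their label, 1 of the 3 labelled erythroid and 1 of the 8 labelled stromal. None of the 4 labelled stromal groups had its arrays as each other's closest among all arrays. The 8 arrays with the stromal profile formed 4 closest pairs with a correlation across genes of 0.9956 to 0.9963, and 0 of these pairs carried a single group label. Of these pairs, 2 joined an array labelled donor A with an array labelled donor B. Every comparison below keeps the labels as deposited, and this limit applies to each of them.

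**Figure D1:**
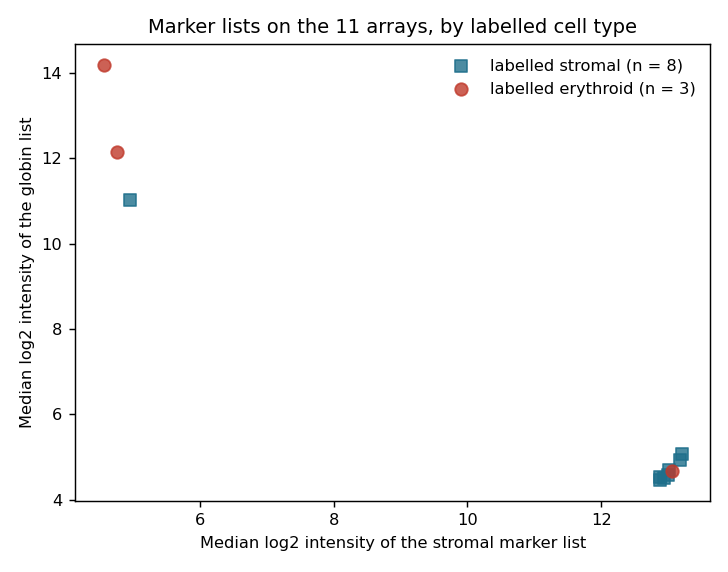
Median log2 intensity of the globin list (vertical axis) against that of the stromal marker list (horizontal axis), 1 symbol per array, with squares for arrays labelled stromal and circles for arrays labelled erythroid. The symbol of 1 array labelled erythroid lies at a globin median of 4.68 and a stromal median of 13.07, among the arrays labelled stromal, and 1 array labelled stromal lies at 11.03 and 4.96, with the erythroid ones.

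The first comparison asked what ACE-011 changed in stromal cells, averaged over both donors. The stromal-labelled array of the other profile is 1 of the 4 treated arrays, labelled donor A, so it enters the treated side of this contrast. No gene passed the test, so the genes described here are those with the smallest unadjusted p in each direction. Each had the same sign in both donors, which their choice by the averaged contrast favours, so it is no separate evidence. PI3, which encodes the elastase inhibitor elafin, had the largest difference among them, at 5.97 on treated and 9.32 on untreated arrays (difference -3.35 ± 0.65 log2, SE, 4 arrays each). Among genes with lower averages were also TENM4, a transmembrane teneurin (-1.33 ± 0.23), and IBSP, the bone sialoprotein of mineralising matrix (-1.06 ± 0.21). CCL4L2, a chemokine gene, was above background on 4 of 4 untreated and 0 of 4 treated arrays, at least 2.38-fold lower on the latter. Its near-identical copies could share the probe, so the gene behind that signal is uncertain. The probe that the file names MIR1974 differed by -1.95 ± 0.39. Genes with higher averages on treated arrays included NET1, an exchange factor that activates RhoA, at 8.95 against 7.54 (1.41 ± 0.27). MAOB, the monoamine oxidase of the outer mitochondrial membrane, was above background on 4 of 4 treated and 1 of 4 untreated arrays, so its difference of 1.14 ± 0.24 is taken against arrays mostly not above background, and it was 0.97 with those at their background level. PI3, TENM4 and IBSP were above background on 3 of 4 treated arrays, with differences of -3.27, -1.22 and -0.94 at that level. DAPK2, a calmodulin-regulated kinase linked to cell death, was above background on 3 of 4 treated and 0 of 4 untreated arrays, at least 1.49-fold higher on the former. CCDC68 differed by 0.94 ± 0.20, and the ribosomal protein pseudogene RPL6P10 by 0.71 ± 0.14, whose signal parent or sister copies could contribute to. Each of these 10 genes had an adjusted p of 0.882 in limma. The file places NET1 on chromosome 10, TENM4 on 11, DAPK2 on 15, CCL4L2 on 17, CCDC68 on 18, PI3 on 20, RPL6P10 and IBSP on 4 and MAOB on X, without naming a genome build.

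Across 16300 genes, limma called 0 at an adjusted p under 0.05 in the averaged contrast. At an unadjusted p under 0.05 it counted 675 genes, 234 higher and 441 lower on treated arrays, where 815 were expected without any effect. In donor A the counts were 0 called and 949 at an unadjusted p under 0.05, with a lowest adjusted p of 0.647. In donor B they were 0 and 41, with a lowest adjusted p of 1. The difference between the donors' effects, tested as an interaction, gave 0 genes and 63 at an unadjusted p under 0.05, with a lowest adjusted p of 0.924. Without the array of the other profile, a choice made after seeing the data, limma called 0 of 15874 genes in the averaged contrast and counted 1663 at an unadjusted p under 0.05, where 794 were expected without any effect. Leaving out instead the array that shares its group left that group with the other profile alone. The fit then set an erythroid profile against stromal ones in donor A and called 4691 genes in the averaged contrast, 6557 in donor A and 4596 for the interaction. With the array of the other profile left out, the differences of NET1 (1.20 ± 0.21), PI3 (-3.14 ± 0.68) and TENM4 (-1.28 ± 0.24) were of similar size, with an adjusted p of 0.439.

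Genes of the activin pathway itself, the target of ACE-011, were read in the same contrast, and none of the 21 measured ligands, receptors and binding proteins passed the test. GDF15, a stress-induced member of the family, differed by -1.56 ± 0.60 between treated and untreated arrays, and GDF5, a growth factor of joint and skeletal development, by -1.04 ± 0.27. FST, which encodes the activin antagonist follistatin, differed by -0.67 ± 0.39, and GDF11, a ligand that ACE-011 binds, by 0.97 ± 0.68. Without the array of the other profile, GDF15 differed by -0.92 ± 0.34, GDF5 by -0.84 ± 0.22, FST by -0.23 ± 0.16 and GDF11 by 0.16 ± 0.13. ACVR2A, the receptor from which ACE-011 derives, differed by -0.17 ± 0.32, and the activin subunit gene INHBB by 0.35 ± 0.32, and they differed by 0.19 ± 0.15 and 0.64 ± 0.26 without that array. The median of this list was -0.18 (camera adjusted p = 0.0476 with a preset correlation, adjusted p = 0.646 with an estimated correlation), and it was 0.16 without the array of the other profile. Targets of the TGF-beta and activin branch of SMAD signalling had a median of -0.81 (adjusted p = 9.45e-05 preset, adjusted p = 0.522 with an estimated correlation), and TGFBI, a secreted matrix protein, differed by -1.93 ± 1.51. Without the array of the other profile, that list's median was -0.03 and TGFBI differed by -0.08 ± 0.20. Targets of the BMP branch had a median of -0.13 while camera's direction was up (adjusted p = 0.945), and their median was 0.33 without that array.

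Other gene groups of the stromal cells were compared in the same way. Of 26 lists, camera with its preset correlation called 19, 2 up and 17 down, while 0 held with an estimated correlation (lowest adjusted p = 0.522) and 0 with fry (lowest adjusted p = 0.215). Cell cycle genes had a median of 0.60 (adjusted p = 2.68e-08 preset, adjusted p = 0.522 with an estimated correlation), and TOP2A, the topoisomerase of dividing cells, differed by 1.48 ± 0.57. Inflammatory genes of the NF-kB pathway had a median of -1.03 (adjusted p = 3.62e-06 preset, adjusted p = 0.522 with an estimated correlation), with the cytokine gene IL1B at -2.40 ± 1.00 and IER3 at -1.43 ± 0.39. Genes of the unfolded protein and amino acid stress response had a median of -0.44 (adjusted p = 8.04e-07 preset, adjusted p = 0.522 with an estimated correlation), with the cystine transporter gene SLC7A11 at -1.56 ± 0.49. Hypoxia and glycolysis genes had a median of -0.37 (adjusted p = 0.000516 preset, adjusted p = 0.522 with an estimated correlation), with PFKFB3, which drives glycolysis, at -1.68 ± 0.42 and LDHA at -0.91 ± 0.26. Without the array of the other profile, the medians of these 4 lists were 0.18, -0.32, -0.32 and -0.36, with TOP2A at 0.83 ± 0.15, IL1B at -3.26 ± 0.80, IER3 at -1.61 ± 0.37, SLC7A11 at -1.24 ± 0.44, PFKFB3 at -1.86 ± 0.42 and LDHA at -0.95 ± 0.27. Macrophage and other blood cell markers had a median of -0.39 (adjusted p = 0.000809 preset, adjusted p = 0.522 with an estimated correlation), with the lysozyme gene LYZ at -1.16 ± 0.33 and CD14 at -1.02 ± 0.46. Without that array the list's median was -0.45, with LYZ at -1.20 ± 0.35 and CD14 at -0.70 ± 0.41.

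Matrix genes depended on the array of the other profile. Extracellular matrix genes had a median of -1.04 over all 8 arrays (adjusted p = 0.00306 preset, adjusted p = 0.646 with an estimated correlation) and of 0.36 without that array, with calls in opposite directions. TNC, a matrix glycoprotein, differed by -2.51 ± 0.95, and the collagen gene COL3A1 by -2.27 ± 1.93. Matrix proteases and their inhibitors had a median of -1.02 (adjusted p = 6.53e-06 preset, adjusted p = 0.522 with an estimated correlation) and of -0.10 without that array, and MMP1, the interstitial collagenase, differed by -3.61 ± 0.81. Erythroid markers had a median of 1.85 on the arrays labelled stromal (adjusted p = 0.0077 preset, adjusted p = 0.522 with an estimated correlation) and of -0.06 without that array, with HBA2 at 1.85 ± 1.54. Without it, TNC differed by -1.46 ± 0.46, COL3A1 by 0.11 ± 0.12, MMP1 by -3.09 ± 0.74 and HBA2 by 0.02 ± 0.49. Leaving that array out gave calls for 15 of 26 lists with the preset correlation and 0 with an estimated one, 9 of them also called in that direction over all 8 arrays, and turned the sign of 10 medians. Adjusted over the list alone, 1 gene passed, IBSP in the osteoblast list, against 0 over all genes tested.

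The second part of the design asked what stroma-conditioned medium changed in erythroid cultures, with 1 array per medium and so without a test. The array labelled as grown in medium of untreated stroma is the erythroid-labelled array that had the stromal marker profile. This comparison therefore sets a stromal profile against an erythroid one, and its differences cannot be read as effects of the medium. That array carried high stromal genes and almost no haemoglobin signal next to the standard array. DCN, which encodes the matrix proteoglycan decorin, stood at 14.32 against 4.35 (log2), at least 582-fold higher, and the collagen genes COL3A1, COL1A2 and COL1A1 were at least 450-fold, 288-fold and 243-fold higher. COL6A3, another collagen, was measured on both arrays and was 228-fold higher. The largest increases also included LBP, which binds bacterial endotoxin (at least 521-fold), and IGFBP4, a carrier of insulin-like growth factors (at least 485-fold). The chemokine genes CXCL5 and CXCL12 were at least 265-fold and 242-fold higher. The carbonic anhydrase CA12, the stromelysin MMP3 and the proteoglycan LUM were at least 350-fold, 319-fold and 233-fold higher.

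Globin genes lay at the other end of this comparison. HBB was at least 597-fold lower on the array labelled as grown in medium of untreated stroma, at 4.71 against 14.28, and HBD at least 563-fold. The probes of HBA1 and HBA2, the alpha-globins, and of HBG1 and HBG2, the fetal gamma-globins, were lower by at least 574-fold, 585-fold and 581-fold for the first 3 and by 504-fold for HBG2, although near-identical copies leave the share of each gene uncertain. AHSP, the chaperone of free alpha-globin, was 341-fold lower, and ALAS2, which starts haem synthesis in red cells, at least 261-fold. The globin pseudogene HBBP1, the carbonic anhydrase CA1 and the anion exchanger SLC4A1 were lower by at least 184-fold, 175-fold and 132-fold. Of the 24 genes that the rule for named genes took, 3 were above background on both arrays and 21 gave bounds. All 14 stromal markers were at least 2-fold higher (list median 6.81, or 6.73 with genes below background at their bound), and all 10 globin genes (-9.16, or -9.06) and all 40 cell cycle genes (-4.37, or -4.17) were at least 2-fold lower. In all, 5126 of 13868 genes differed at least 2-fold, 2652 higher and 2474 lower, and 23 of 27 lists lay outside the middle range of random lists. The same count between the arrays of each labelled stromal group was 81, 455 and 949, and 5939 in the group that holds the array of the other profile. With the arrays' medians set equal in place of their whole distributions, the median of all genes moved from -0.12 to -0.22 and the split was 2629 higher and 2953 lower.

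The next comparison asked how medium of ACE-011-treated stroma differed from medium of untreated stroma for these cultures. Globin and mast cell genes were higher on the array labelled as grown in medium of treated stroma. HBG1 and HBG2, whose near-identical sequence leaves the share of each uncertain, were higher by at least 468-fold and by 391-fold, HBB and HBA2 each at least 226-fold, HBE1, the embryonic epsilon-globin, at least 173-fold, HBD at least 124-fold and ALAS2 at least 115-fold. HDC, the enzyme that makes histamine, stood at 14.02 against 5.53 and was 358-fold higher. CPA3, a protease of mast cell granules, GATA2, a transcription factor of progenitors and mast cells, FCER1A, a chain of the IgE receptor, and KIT, the receptor for stem cell factor, were higher by at least 173-fold, at least 114-fold, 114-fold and at least 88.4-fold. Stromal genes were lower, with DCN at least 523-fold, LBP 469-fold, IGFBP4 436-fold, COL3A1 404-fold, TGFBI 383-fold and CA12 314-fold as lower bounds. For MMP3, COL1A2, COL6A3, CXCL5, COL1A1 and CXCL12 the bounds were 287-fold, 259-fold, 250-fold, 239-fold, 218-fold and 218-fold.

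By list, 8 of 9 globin genes were at least 2-fold higher with medium of treated stroma (median 8.17, or 7.44 with genes below background at their bound), as were 13 of 14 mast cell, basophil and eosinophil genes (5.58, or 5.12) and 34 of 37 cell cycle genes (1.79, or 1.65). All 14 stromal markers (-6.16, or -5.92) and 22 of 28 TGF-beta and activin targets (-3.17, or -2.81) were at least 2-fold lower. The array labelled as grown in medium of untreated stroma, the reference here, is the one among the 3 with the stromal marker profile. In total 5676 of 13719 genes differed at least 2-fold, 2976 higher and 2700 lower. With the medians set equal, the median of all genes moved from -0.01 to -0.52 and the split was 1707 higher and 4467 lower.

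The third erythroid comparison set the medium of treated stroma against the standard medium, on 2 arrays that both had the erythroid marker profile. Genes of the red cell membrane were lower with the medium of treated stroma, and genes of mast cells and basophils were higher. This pattern was not confined to that label: 1 array labelled stromal, with the erythroid profile, had medians of 6.18 for membrane and 11.43 for mast cell genes. On the array labelled as grown in medium of treated stroma they were 6.14 and 11.24, and on the standard array 10.26 and 8.28. The closest pair among the 3 arrays with the erythroid profile held 1 array labelled stromal and 1 labelled erythroid and differed 2-fold in 284 of 13796 genes. The other pairs, both with the standard array, differed in 3759 and 4144. AHSP stood at 5.63 against 13.56 (log2), 244-fold lower, and SLC4A1, the anion exchanger of the red cell membrane, was at least 112-fold lower. HBM, a globin of the alpha cluster, and EPB42, which links the membrane to its skeleton, were at least 92.6-fold and 56.3-fold lower, and CA1 was 52.8-fold lower. DHRS9, a retinol dehydrogenase, and PTGS2, the inducible cyclooxygenase, were at least 66.9-fold and 39.8-fold higher. MIIP, which binds an insulin-like growth factor carrier, CROT, a peroxisomal carnitine transferase, and HPGD, which degrades prostaglandins, were 36.1-fold, 33.7-fold and 31.1-fold higher.

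Of 28 erythroid membrane and cytoskeleton genes, 27 were at least 2-fold lower and none was at least 2-fold higher with the medium of treated stroma (median -3.02, or -2.85 with genes below background at their bound). Haem synthesis and iron genes had a median of -1.18, with 14 of 23 at least 2-fold lower, among them FECH (15.7-fold) and ALAD (11.7-fold), both enzymes of the haem pathway. Globins had a median of -1.79, with 7 of 10 at least 2-fold lower, yet HBE1 was 29-fold higher, at 12.50 against 7.64. Among erythroid transcription and erythropoietin signalling genes (median -0.42, or -0.23), KLF1, an activator of adult globin genes, and BCL11A, a repressor of fetal globin genes, were 6.48-fold and 6.78-fold lower, and GATA2 was 17.1-fold higher. Of 14 mast cell, basophil and eosinophil genes, 11 were at least 2-fold higher and none at least 2-fold lower (median 3.24), including the lectin SIGLEC6 (at least 23.9-fold), CPA3 (17.4-fold) and HDC, at 14.02 against 9.98. Both directions held under each scaling tried, with the mast cell list at 2.79 when the medians were set equal.

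Of 40 cell cycle genes, 39 were at least 2-fold lower (median -2.53), with RRM2, a subunit of ribonucleotide reductase, 11.2-fold and the kinesin KIF20A 10.1-fold lower. MYC targets and ribosome biogenesis genes had a median of -1.31, with 14 of 21 at least 2-fold lower, among them ODC1, which starts polyamine synthesis (10.5-fold), and MYC itself (4.23-fold). Mitochondrial oxidative phosphorylation genes had a median of -1.01, with 13 of 23 at least 2-fold lower. Inflammatory genes of the NF-kB pathway had a median of 1.38, with 10 of 15 at least 2-fold higher, including the cytokine gene LIF (9.07-fold) and the apoptosis inhibitor BIRC3 (7.93-fold). Myeloid genes went both ways, with 10 of 30 at least 2-fold higher and 8 at least 2-fold lower. CD33, a myeloid surface lectin, was 22.8-fold higher, while the granule proteins AZU1, PRTN3 and MPO were 9.31-fold, 7.87-fold and 6.37-fold lower. In the activin list FST was at least 15.8-fold and GDF11 4.89-fold higher and GDF15 3.55-fold lower, and the list's median was 0.72. Of 27 lists, 6 lay above and 9 below the middle range of random lists of matched size and intensity. In total 4470 of 12820 genes differed at least 2-fold, 2308 higher and 2162 lower. With the medians set equal, the median of all genes moved from -0.08 to -0.67, that of the activin list moved with it to -0.15, and the split was 1148 higher and 4760 lower.

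**Figure D2:**
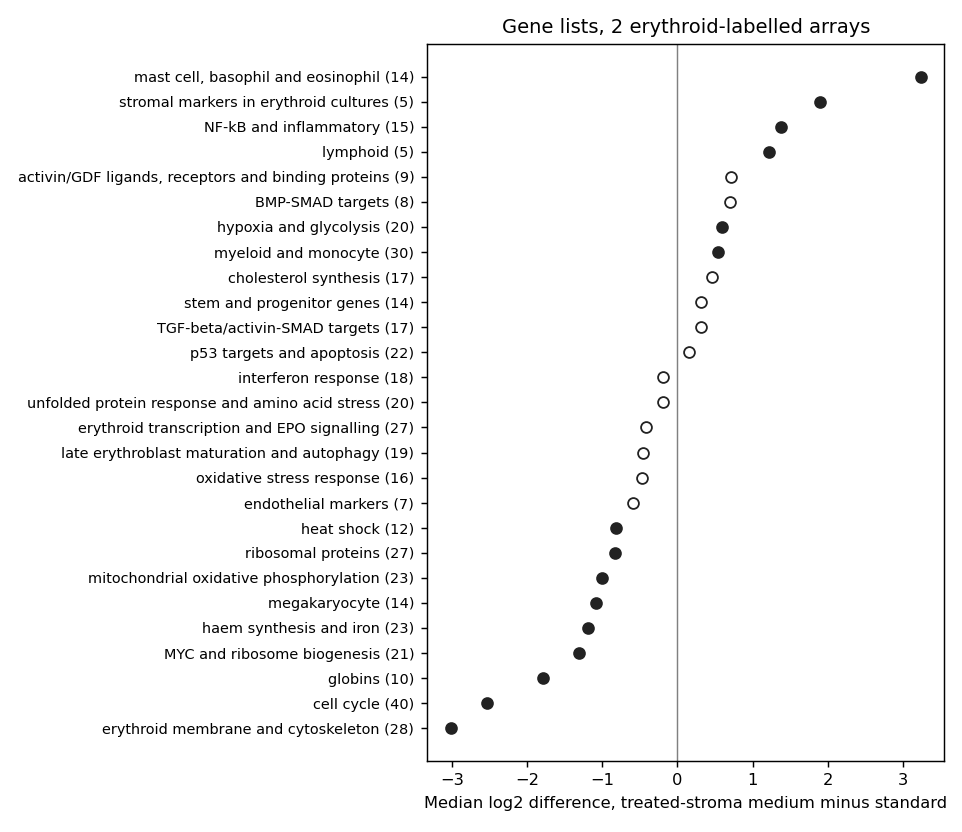
Median log2 difference of each gene list (horizontal axis) between the array labelled as grown in medium of treated stroma and the standard array, with the number of genes measured in brackets; filled symbols lie outside the middle 95% of random lists. Erythroid membrane genes lie at -3.02 and mast cell genes at 3.24, and the activin list lies at 0.72, within the range of random lists.

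**Figure D3:**
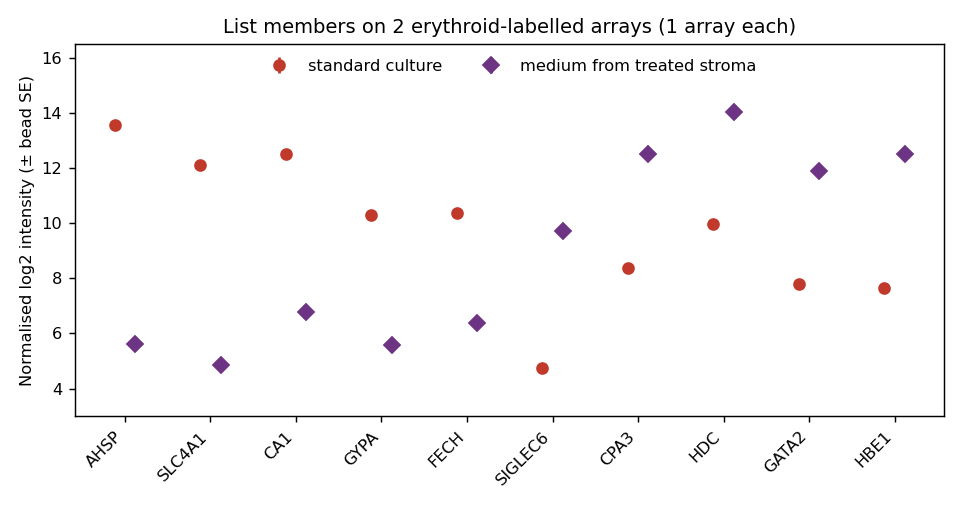
Normalised log2 intensity (vertical axis) of 10 list members on the standard array (circles) and on the array labelled as grown in medium of treated stroma (diamonds), 1 array each, with bead standard errors smaller than the symbols. AHSP goes from 13.56 on the standard array to 5.63 and HDC from 9.98 to 14.02, and SLC4A1 is not above background with the medium of treated stroma.

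The last comparison asked how far medium of treated stroma brought genes back from their level with medium of untreated stroma towards the standard level. Among the 5126 genes that differed at least 2-fold between untreated-stroma medium and standard, such as the collagen and globin genes named above, the median change was 1.70 (log2) and the median move back towards standard was 1.31. In total 3268 genes (63.8%) went past the middle of the way. A simulation in which both conditioned media were alike, with noise drawn from the labelled stromal groups, gave a median of 0.19 and 20.4% of genes, and 0.09 and 7.04% without the group that holds the array of the other profile. The comparison runs through the array labelled as grown in medium of untreated stroma, on which COL1A1 stood at 13.06 and HBB at 4.71, against 4.60 and 14.28 on the standard array. Genes that part these profiles return on an array with the erythroid profile whatever the medium did, so neither the share nor the simulation measures a return due to the medium.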

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

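Leaving out the stromal-labelled array of the other profile, a crossed replicate block, with the numbers of donor A's treated arrays exchanged, and a noise estimate without that array's group were chosen after seeing the data. Apart from the exceptions that follow, limma called 0 genes in the averaged contrast under each alternative, leaving out the array of the other profile included. Leaving out each stromal array in turn gave 0 to 4691 genes in the averaged contrast, 0 to 6557 in donor A, 0 to 4596 for the difference between donors and 0 to 0 in donor B. The highest counts (2330 higher and 2361 lower in the averaged contrast) came without the array that shares a group with the array of the other profile, which leaves the erythroid profile alone in that group, assumed to vary like the other groups, so that fit compares cell types in donor A. Medians then went from 1.85 to 3.72 for erythroid markers and from -1.04 to -2.55 for extracellular matrix. A replicate block by donor and number gave 7 genes (2 higher, 5 lower) and the crossed block 17 (3 and 14), and the cause was not tested. The numbers do not pair the samples, since both treated arrays of donor B carry number 2. Deviations of same-numbered groups correlated at -0.198, -0.047 and -0.231. The first and last of these involve the group with the array of the other profile, so they cannot tell whether numbers pair samples. Of 26 stromal lists, 19 were called with camera's preset correlation, 14 to 20 on leaving out arrays, 13 to 19 under the other settings, 0 with an estimated correlation, which by construction lets correlated genes count for less, and 0 with fry, where the cause was not tested. The 10 named stromal genes kept their sign in up to 24 settings, with 224 values on the same side of the threshold and 10 past it, each in that fit of an erythroid profile against stromal ones. The counts of 2-fold erythroid genes (5126, 5676 and 4470 for untreated-stroma medium against standard, treated against untreated, and treated against standard) were 3392 for the first and 2894 for the third with normexp without negative controls, 2676, 3087 and 2327 without background correction, and 2736, 3157 and 2376 in the authors' table, where background stays in each value. With genes detected on both arrays, fewer were compared and the counts were 3235, 3603 and 3445. For the second, 10 lists lay outside the limits in place of 18. By construction, 1.5-fold gave 8172, 8686 and 7711 and 3-fold 2828, 3258 and 2063. The share moved back towards standard, 63.8%, was 55.8% under median scaling and 57.4% for genes detected on both arrays, and the cause was not tested. None of 58 named erythroid results changed sign, and 13 of 81 list results did, in 14 values. Of these values, 11 came under median scaling, which shifted all genes. The direction of those lists therefore depends on the scaling and is not settled. Signals near background limit all folds given as bounds.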

Other observations

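The first paragraphs give values, and the tests of explanations further on were all chosen after the result was seen, except the 2 counts of splits, which were planned. Several macrophage genes were high on the 8 arrays with the stromal profile, and the genes given were chosen after their values were seen. CD14, the co-receptor for endotoxin, stood between 11.64 and 13.45 (log2) and CD68, a lysosomal protein of macrophages, between 11.81 and 12.97 on these 8 samples. HLA-DRA, which presents antigen, stood between 12.22 and 13.31, and CD163, the haemoglobin scavenger receptor, between 8.85 and 10.73. On the 3 samples with the erythroid profile, CD163 stood between 4.52 and 5.71, CD14 between 10.18 and 11.20, CD68 between 9.49 and 11.84 and HLA-DRA between 11.56 and 12.31, so the last 2 overlapped. LYZ (10.03 to 11.98 against 9.78 to 12.06) and CD74 (11.64 to 12.53 against 11.28 to 12.24) overlapped as well.

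Smaller groups of the third erythroid comparison, medium of treated stroma against standard, add detail. Megakaryocyte genes had a median of -1.09, with CLEC1B, a receptor of platelets, 10.8-fold and PPBP, a platelet chemokine, 6.19-fold lower. Ribosomal protein genes had a median of -0.83, with 9 of 27 at least 2-fold lower. Heat shock genes had a median of -0.82, and HSPE1, a mitochondrial chaperonin, was 2.84-fold lower. The glucose transporter gene SLC2A1 of red cells was 12.5-fold lower while SLC2A3, another glucose transporter, was 5.71-fold higher. Targets of the BMP branch went both ways and lay within the range of random lists, with 4 of 8 at least 2-fold higher and 2 lower. HEY1 and ID2 were at least 17.5-fold and 4-fold higher, and ID1 was at least 3.03-fold lower.

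The marker profile of 2 arrays was that of the other cell type, 1 labelled erythroid and 1 labelled stromal. A mixture of both cell types is argued against. The abundant markers of the labelled type stood at medians of 0.105% and 0.179% of their level on arrays with that profile. Among the 10 stromal markers, VIM stood at 37.9% and SPARC at 3.39%. Weak hybridisation is argued against too, since at least 380 genes outside the lists stood 2-fold or more above every other array of the label on each of the 2, while detected probes lay below the range of the other 9 on 1 array at a detection p under 0.05 and on 0 under 0.01. An exchange of these 2 labels as the only label error is not settled by the other 3 groups, which it leaves alone. Their arrays differed 2-fold in 78 to 925 genes, while the closest pairs, which cross the group labels, differed in 1 to 3. The closest pairs were chosen for being alike, so a smaller count in them is no test. The stromal group that the exchange forms differed in 767 genes, between 78 and 925, and so cannot decide. An error on other arrays as well stays open. Groups whose arrays were each other's closest numbered 0 of 4 before the exchange and 0 of 4 after it, although it could change only 1, and no biological explanation was tested.

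The 8 arrays with the stromal profile formed 4 closest pairs, and 0 of 4 pairs carried a single group label, which 3 of them could have. The labelled pair with the fewest 2-fold genes had 78, and the closest pairs had 1 to 3, so arrays with like labels were not the most alike. This cannot exclude differences between groups too small to see. The closest pairs were chosen for being alike, and a large spread within labels could hide such differences. The 2-fold counts of these label checks cover 13796 genes with all 11 arrays normalised together. They therefore differ from the 81, 455 and 949 given for the labelled stromal groups above. Neighbouring chip positions are argued against, since 0 of 4 closest pairs were neighbours. Labels wrong on more than 2 arrays could give the pattern and stay open. The count of 0 of 4 closest pairs with 1 label is the pattern itself, so it is no test of this hypothesis. Of the 3 pairs labelled stromal on both arrays, 2 shared the dose label and 1 did not. Since 0 pairs carried a single group label, those 2 pairs joined an array labelled donor A with an array labelled donor B. Whether the ACE-011 contrast mixes treated and untreated samples stays open. The donor labels, on which the results per donor and the interaction rest, are in doubt as well. For probes detected on every array, differences within the closest pairs were 1.16 to 1.27 times those expected from the bead standard errors. Within the labelled pairs they were 1.97 to 8.38 times. A biological difference between cultures with like labels was untested. It stays open for the spread within labels, but would not by itself make arrays of different donor labels this alike.

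Erythroid membrane genes were lower and mast cell genes higher with medium of treated stroma than in standard culture. The array of treated-stroma medium had a mean signal of 228.2, against 357.5 on the standard array. The stromal-labelled array with the same pattern had 240.5, and all other arrays had 307.3 or more. A dimmer array is argued against as the whole cause, since the mast cell list still had a median of 2.79 with the arrays' medians set equal. Whether dimness lowered the membrane genes was not tested. A lower share of erythroid cells alone would move the lists of other blood lineages up together, and they did not move together. With 1 array per medium these lists cannot decide it, so it stays open. The megakaryocyte list had a median of -1.09 while the mast cell list had 3.24. The lymphoid, myeloid and stem and progenitor lists had medians of 1.22, 0.535 and 0.31. With the arrays' medians set equal, those of the myeloid and the stem and progenitor lists were -0.27 and -0.42. A mislabelled array cannot be told apart from an effect of the medium, because there was 1 array per medium and an array labelled stromal carried the same pattern (6.18 and 11.43 against 6.14 and 11.24 for the membrane and mast cell medians). An effect of the conditioned medium on the cultures stays open as a possible explanation.

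With 2 groups of 4 stromal-labelled arrays, 35 splits were counted with an additive donor model, except for the 1 split equal to the donors, fitted without it. For genes called, 35 of 35 splits had to give as many as the real 0, so that count says nothing about chance, although the highest other split gave 32 and only 1 split called any. For gene lists called with the preset correlation, the real split gave 17 and the highest other 20, and 11 of 35 gave as many, as did 7 of the 18 with 2 arrays per donor on each side, so chance is not excluded for the lists. At an unadjusted p under 0.05 the real split counted 744 genes, and 9 of 35 splits, itself included, counted as many. The highest other count was 4033, in a split unbalanced between the donors, and 1239 among those 18. What drives the highest counts was not tested.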
